A study of Mus musculus with 3 samples.

How the data were processed

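Androgen receptor (AR) and dimethylated lysine 4 of histone H3 (H3K4me2) were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb muscle of C57BL/6 mice aged 9 weeks. The series holds 3 libraries, 1 from the AR immunoprecipitation, 1 from the H3K4me2 immunoprecipitation and 1 from input chromatin. The titles name limb muscle for all 3 libraries, while the source field of each names limb and bulbocavernosus muscles, so the muscle is given here as in the titles. Peak lists of the AR and H3K4me2 libraries were analysed, and no values of the input library were analysed here.

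Per the series' design text, muscle nuclei were extracted, chromatin was sonicated and immunoprecipitated, and libraries were read as paired ends of 100 bp on an Illumina HiSeq instrument. Reads were mapped to mm10 with Bowtie 2, uniquely mapped reads were kept, and MACS2 called peaks against chromatin that had not been immunoprecipitated. Per the labels, libraries were made with the MicroPlex Library Preparation kit v3, which joins adaptors to blunt-ended DNA and adds indexes by PCR. The submitters' processing notes name bcl2fastq 2.20.0.422. The versions and options of MACS2 and Bowtie 2 were not given in the sources used here.

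Each deposited list has 1 line per peak with the start, end and summit offset in bp from the peak start. The deposited fold enrichment is the ratio of the pileup of fragments at the summit to the local background that the authors' MACS2 run estimated from the input. The deposited p and q values are on the −log10 scale, and the deposited score was the whole-number part of 10 times −log10 q in all 4691 AR and all 60262 H3K4me2 peaks. The lowest deposited −log10 q was 1.02 in the AR list and 1.30 in the H3K4me2 list, so the thresholds of the lists differed. All peaks lay on named chromosomes, and 0 ended past the end of one in the GRCm38.p6 sequence, the build called mm10. Peaks on chromosomes 1 to 19, X and Y were used, which left out 2 AR peaks on the mitochondrial genome.

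Read totals were not in the files. The pileup behind each peak was recovered from its fold enrichment and p value, as the fold is the pileup plus 1 over the background plus 1 and p is the Poisson tail above the pileup. A whole number of fragments solved both values within 0.001 for 100% of AR peaks and 99.96% of H3K4me2 peaks. These pileups are called fragments below. They count aligned fragments at the summit, which are not independent molecules where PCR copies were kept. The lowest background among the peaks, a measure of library depth after scaling, was 0.274 fragments for AR and 1.19 for H3K4me2, a ratio of 4.35. With 1 library per group there were no replicates, and no test between libraries was possible. Peaks of 1 library are not replicates, and tests over peaks describe these lists alone. Shares of peaks or genes carry exact Clopper-Pearson 95% binomial intervals, which cover counting error only.

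AR peaks overlapped H3K4me2 peaks when they shared at least 1 bp, and the number of such AR peaks was the same when counted with bedtools 2.31.1. The background was 1000 random placements of the AR peaks on their own chromosomes outside assembly gaps, with widths kept and a fixed seed. Placements were not limited to sequence where reads map uniquely. The 2-sided p values double the smaller share of placements at or beyond the real value, with the real peaks counted as 1 placement, so the smallest possible was 0.00200. Alternatives of the promoter share used 200 of these placements, with a smallest possible p of 0.00995. Peaks were assigned to promoters (summit within 1 kb of a start site in GENCODE release M21), exons, introns or intergenic sequence, in that order. Medians were compared by 2-sided permutation tests with 100000 resamples.

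Sequence was searched on both strands within 100 bp of the summit for 20 consensus motifs. The androgen response element was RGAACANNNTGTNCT with at most 2 mismatches, and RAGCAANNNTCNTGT, the same letters in another order, was its control. The background was H3K4me2 peaks without AR, drawn to the same counts in bins of 5 GC points. In low-GC bins the H3K4me2 peaks ran short, so equal numbers were drawn from both lists, which left 2972 peaks on each side and 1717 AR peaks outside the matched comparison. That equal draw was adopted once the shortfall was seen. Shares were compared with 2-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 20 motifs at a threshold of 0.05.

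Each AR peak was assigned to the protein-coding gene with the nearest start site within 100 kb. For each of 29 gene lists, the number of members with an AR peak was placed among 10000 random lists of equal size. Random lists were matched on H3K4me2 within 1 kb of the start site and on deciles of territory, the stretch of genome nearest to a gene's start site. The lists cover 20 pathways, 7 other cell types of limb muscle, and liver and neurons. All members of all lists were in the annotation of 21826 protein-coding genes. Percentiles of lists are descriptions and not p values, and in simulated data 8.50% of random lists lay above the 95th percentile. The simulation used 200 lists of 25 genes matched on territory only, with genes near a peak drawn evenly. Its rate may therefore differ from that of the 29 lists, some of which also share members.

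The comparisons, tests, gene lists, motifs, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule named the 20 AR peaks of highest fold enrichment with their genes, and from each list up to 4 members with the highest AR peaks and up to 3 members without one. It also named the 5 genes with most AR peaks, the 10 widest H3K4me2 peaks, all members of the androgen and polyamine lists, and Ar. Where a gene outside the rule is given, this is stated.

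Dinucleotide repeats became a subject of the analysis once AR peak sequences had been looked at. A repeat was a run of at least 20 positions each equal to the base 2 positions earlier, with runs of a single base left out, and a peak was at a repeat when it overlapped one. All other peaks are called away from repeats, although some of them lay beside one. The first definition tried asked for 20 positions of the run within 100 bp of the summit, and it was kept as an alternative when runs at peak edges were found to be missed. Backgrounds were windows 2 kb to either side of each AR summit (9378 windows of the AR peaks' widths), random placements, and windows of 103 bp to either side of H3K4me2 summits. Each result was recomputed with alternative overlaps, thresholds, distances, backgrounds, matching rules and mismatch numbers, and without AR peaks at repeats. The methods were tested on simulated data, in which 100% of planted motifs, repeats and pileups were recovered and 5.50% of median tests without a difference fell below 0.05. The planted motifs were perfect response elements sought with 0 mismatches, so calls at 2 mismatches were not tested in this way. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.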

Results

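Peak lists were available for 1 AR library and 1 H3K4me2 library from limb muscle of C57BL/6 mice aged 9 weeks, each called against 1 input library. AR is the nuclear receptor that androgens activate, and H3K4me2 marks promoters and enhancers. There were no replicates, so no value below carries an error between libraries. Read totals were not given, and depth is described by the fragments stacked at each peak summit. AR peaks rested on 4 to 16 fragments with a median of 5, and 3369 of 4689 (71.8%) rested on 4 or 5. H3K4me2 peaks rested on 6 to 240 fragments with a median of 19. The background under H3K4me2 peaks started at 1.19 fragments, against 0.274 for AR. Intervals are exact 95% binomial intervals and cover counting error only.

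The first question was which regions of muscle chromatin the AR library marked. The 4689 AR peaks on chromosomes 1 to 19 and X covered 1.08 Mb and had a median width of 206 bp (interquartile range 176 to 263). Their fold enrichment over input had a median of 4.71 (interquartile range 3.92 to 5.25) and a maximum of 12.5, and 245 peaks (5.22%) reached a −log10 q of 5. The highest peak lay in an intron of chromosome 6 (83159530 to 83160025, mm10), 3.23 kb from the start site of 1700003E16Rik, with 16 fragments and a fold enrichment of 12.5. Of the 20 highest peaks, 11 had a protein-coding start site within 100 kb. These included Fli1, an ETS transcription factor (chromosome 9, 32526666 to 32526884, fold 11.0), and Asph, which encodes aspartyl hydroxylase and the calcium-handling protein junctin (chromosome 4, 9696212 to 9696555, fold 10.2). The others were Sdk1, Prr5, Epb41l3, Tmem241, Btbd9, Tfpi, St6galnac3 and Prep. Of these 20 peaks, 0 overlapped an H3K4me2 peak and 20 overlapped a dinucleotide repeat, with the unit AG/CT in 12 and AC/GT in 8.

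Most AR peaks overlapped a repeat of AC/GT or AG/CT. Of the 4689 peaks, 3705 (79.0%, 77.8 to 80.2) overlapped a dinucleotide repeat, against 438 of 9378 windows 2 kb away (4.67%, odds ratio 76.9). The share was 3.81% in random placements, 2.91% around all H3K4me2 summits and 8.01% around H3K4me2 summits of matched GC content. The unit was AC/GT in 2320 of the repeat peaks (62.6%), AG/CT in 1378 (37.2%), AT in 7 (0.189%) and CG in 0. This comparison was chosen after the peak sequences had been seen. The share with a repeat was higher with more fragments, from 72.8% of 1875 peaks with 4 fragments (70.7 to 74.8) and 77.0% of 1494 with 5 to 88.4% of 1051 with 6 or 7 and 97.03% of 269 with at least 8 (94.2 to 98.7). When 20 positions of the run had to lie within 100 bp of the summit, the share was 49.8% (3.34% in windows 2 kb away), and within 50 bp it was 18.4% (1.76%).

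**Figure D1:**
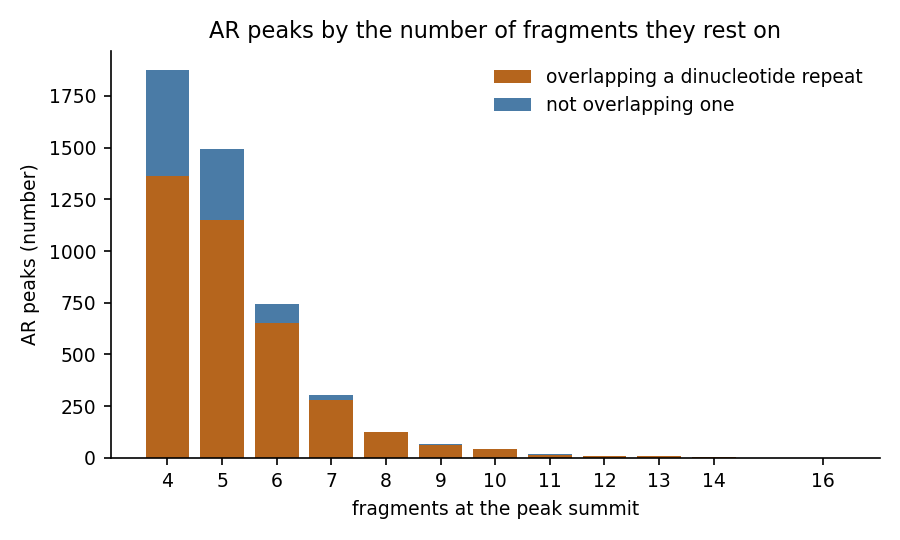
Number of AR peaks (vertical axis) by the number of fragments at the peak summit (horizontal axis), divided into peaks that overlap a dinucleotide repeat (brown) and peaks that do not (blue). Most peaks rest on 4 or 5 fragments (3369 of 4689), and the share at a repeat is 72.8% with 4 fragments and 97.03% with at least 8.

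AR summits lay beside these repeats more often than on them. The summit was on the repeat in 8.68% of AR peaks, 1 to 24 bp away in 7.36%, 25 to 49 bp away in 13.8% and 50 to 74 bp away in 17.3%. In windows 2 kb away the largest of these shares was 0.864%, and 0.725% lay on a repeat. Among peaks that met a repeat, the summit was on the longest one in 9.18% of AR peaks and 14.8% of random placements. Placements too thus lay mostly beside repeats. Among the 3705 repeat peaks, the outer end of the repeat lay within 25 bp of a peak edge in 82.5% (81.3 to 83.7), against 37.9% (35.6 to 40.2) of 1788 random placements that met a repeat. Of the AC/GT repeats in the genome, 0.612% of those of 22 to 29 bp and 2.12% of those of 60 to 79 bp overlapped an AR peak, and 1.09% of all 260671 did. For AG/CT repeats the shares were 0.803% and 1.77%, and 1.40% of all 117240. Longer repeats are also met more often by chance. For windows of AR peak width around H3K4me2 summits the shares were 0.468% and 1.37% for AC/GT and 0.257% and 0.316% for AG/CT. These came from 60262 windows, against 4689 AR peaks, so the shares are not rates per peak. Of 36511 AT repeats, 19 (0.0520%) overlapped an AR peak.

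**Figure D2:**
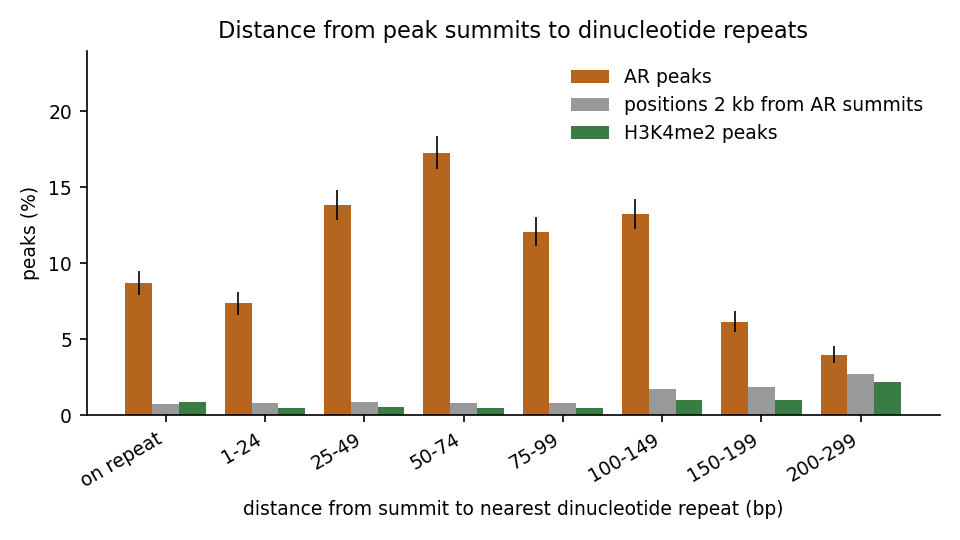
Share of summits (vertical axis, %) by distance to the nearest dinucleotide repeat (horizontal axis, bp) for AR peaks (brown, with exact 95% binomial intervals), positions 2 kb from AR summits (grey) and H3K4me2 peaks (green). AR summits are most frequent 50 to 74 bp from a repeat (17.3%), where positions 2 kb away reach 0.778%. Bins are wider from 100 bp on.

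H3K4me2 marked the start sites of most genes in the pathway lists. Of the 456 members of the 20 pathway lists taken as a union, 433 (94.96%, 92.5 to 96.8) had an H3K4me2 peak within 1 kb of a start site, as had 14148 of 21826 protein-coding genes (64.8%). The share was 54 of 90 (60%, 49.1 to 70.2) for markers of other cell types of limb muscle and 11 of 30 (36.7%, 19.9 to 56.1) for liver and neuron markers, 58.3 points below the pathway lists. All members of the myogenic transcription factor list (27 genes), the nuclear receptor and coregulator list (34), the insulin, IGF and mTOR list (29) and the circadian clock list (22) were marked. So were all members of the amino acid and creatine list (24), the dystrophin complex list (24) and the satellite cell list (12). In the contractile lists, which share members, 33 of 39 sarcomere genes (84.6%, 69.5 to 94.1), 14 of 16 fast fibre genes (87.5%, 61.7 to 98.4) and 12 of 15 slow fibre genes (80%, 51.9 to 95.7) were marked, and Myh1, Myh2, Myh7 and Tnni1 were among those not marked. Of the 14 immune markers, 1 was marked, and of the 15 liver markers 2 were, while 9 of 15 neuron markers (60%) were. The list held 60262 peaks over 52.6 Mb, with a median width of 555 bp (interquartile range 299 to 1154), a median fold enrichment of 6.28 (interquartile range 4.38 to 12.8), and a −log10 q of at least 5 in 44765 (74.3%).

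**Figure D3:**
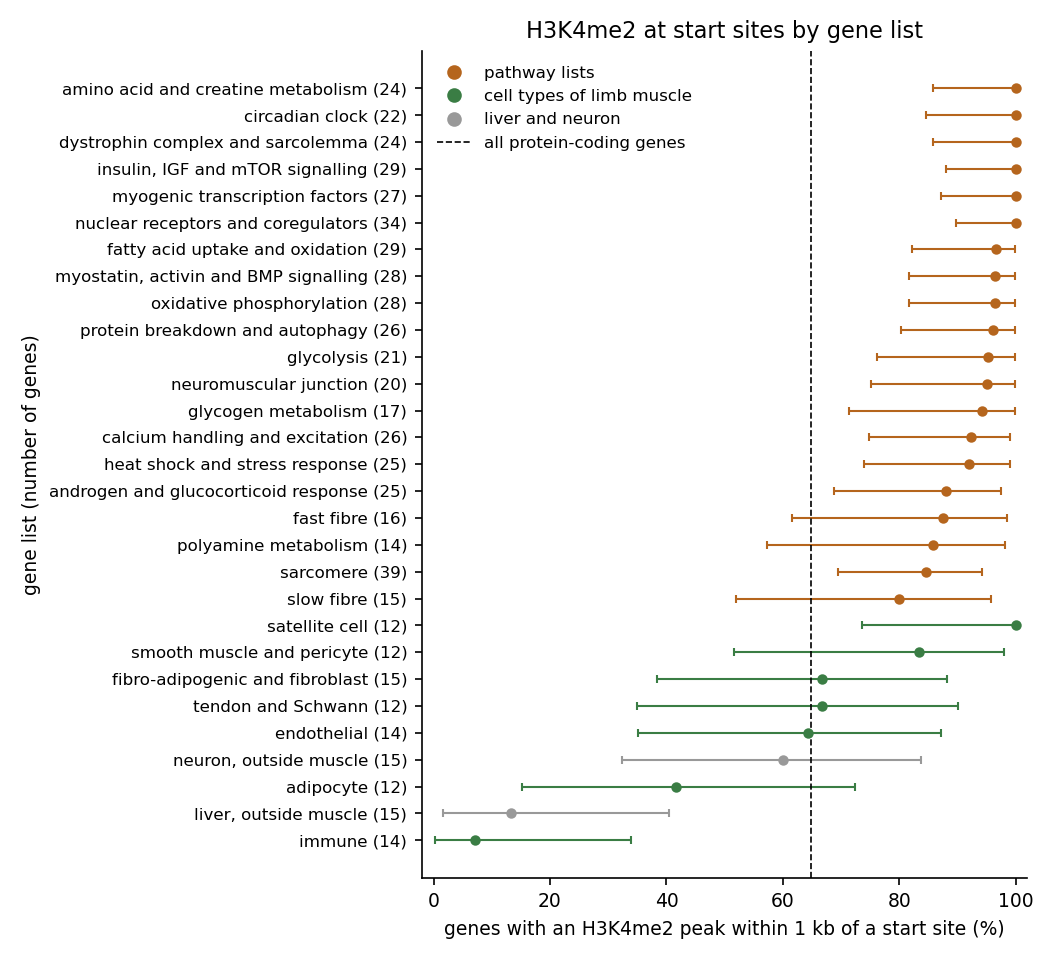
Share of genes with an H3K4me2 peak within 1 kb of a start site (horizontal axis, %) for each gene list (vertical axis, number of genes in brackets), with exact 95% binomial intervals. The dashed line is the share of all protein-coding genes (64.8%), and all 20 pathway lists (brown) lie above it, while the immune list lies at 7.14%, the liver list at 13.3% and the neuron list at 60%.

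The widest H3K4me2 peak covered 21090 bp at Nfic (chromosome 10, 81406633 to 81427722, fold 33.5), a transcription factor of the NF1 family. Next came Mef2d (14445 bp), a transcription factor of muscle differentiation, and Gse1 (14170 bp). The others of the 10 widest were at Smtnl2, Bcl9l, Klf15, Adssl1, Ctdsp2, Kdm6b and Mknk2, from 13885 to 13051 bp. Klf15, a glucocorticoid-induced regulator of amino acid and lipid metabolism in muscle, lay under 13523 bp, and Adssl1, the muscle adenylosuccinate synthase of the purine nucleotide cycle, under 13410 bp. Ar itself carried an H3K4me2 peak of 3426 bp at its start site (chromosome X, 98148172 to 98151597, fold 8.97) and no AR peak within 100 kb was assigned to it. Of the 25 androgen and glucocorticoid response genes 22 were marked, among them Fkbp5, a chaperone of steroid receptors (2720 bp, fold 29.4), Zbtb16 (6310 bp), Klf9 (8120 bp) and Per1 (4753 bp). Of the 14 polyamine genes 12 were marked, among them Odc1, the first enzyme of polyamine synthesis (1591 bp), and Smox, spermine oxidase (2374 bp).

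The next question was whether AR peaks lay in H3K4me2-marked chromatin. Of the 4689 AR peaks, 162 (3.45%, 2.95 to 4.02) overlapped an H3K4me2 peak, against a mean of 2.69% (central 95% 2.24 to 3.18) in random placements on the same chromosomes, a 1.28-fold excess (p = 0.00400, n = 4689). Peaks with and without a repeat differed. Peaks away from repeats were those that overlapped none, and some of them lay beside one. A repeat lay within 300 bp of the summit in 3870 of the 4689 AR peaks (82.5%), and 3705 overlapped one. For positions 2 kb away the share within 300 bp was 10.2%. Of the 984 peaks away from repeats, 69 (7.01%, 5.50 to 8.79) overlapped H3K4me2, against 2.71% in placements (2.59-fold, p = 0.00200, the smallest possible, n = 984). Of the 3705 peaks at repeats, 93 (2.51%, 2.03 to 3.07) did, against 2.68% (0.938-fold, p = 0.579, n = 3705). The placements were not kept to repeats, which were met by 2.91% of windows around H3K4me2 summits and 3.81% of placements. The share expected for peaks at repeats may therefore be lower than 2.68%. Nor were placements kept to sequence where reads map uniquely, while both lists came from uniquely mapped reads. Placements outside such sequence may seldom meet an H3K4me2 peak. This could account for part of each excess over placements given here, also within 50 kb, and was not tested. The peaks away from repeats were also the lower ones, with a median fold enrichment of 3.92 and 4 fragments, against 4.71 and 5 at repeats. With placements kept within 50 kb of each AR peak, the excess was 1.08-fold for all peaks (p = 0.344, n = 4689) and 1.70-fold away from repeats (p = 0.00200, the smallest possible, n = 984). With H3K4me2 peaks of a −log10 q of at least 5 the excess over placements on the chromosome was 1.18-fold (p = 0.0759, n = 4689), and for the AR peaks of that level it was also 1.18-fold (p = 0.735, n = 245). Among H3K4me2-overlapping peaks were those at Hspb1, a small heat shock protein (chromosome 5, 135905445 to 135905679, fold 5.86), and at Abcc9, the regulatory subunit of the muscle KATP channel (chromosome 6, 142703177 to 142703347, fold 4.64), and both lay at a repeat.

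**Figure D4:**
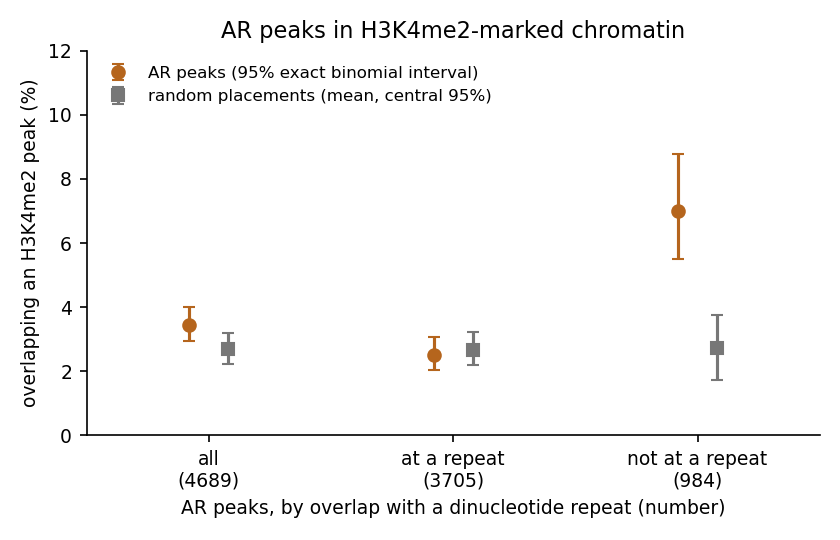
Share of AR peaks that overlap an H3K4me2 peak (vertical axis, %) for all AR peaks, those at a dinucleotide repeat and those not at one (horizontal axis, number of peaks in brackets). Brown points carry exact 95% binomial intervals, and grey squares are the mean of random placements with their central 95%. Peaks not at a repeat stand at 7.01% against 2.71%, and peaks at a repeat at 2.51% against 2.68%. Placements were on the same chromosome and were not kept to repeats or away from them, nor to sequence where reads map uniquely.

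The share of AR peaks at promoters was close to that of random placements. Promoters held 295 of them (6.29%, 5.61 to 7.02), against 6.22% of placements (p = 0.825, n = 4689) and 33.6% of H3K4me2 peaks. Of the same peaks, exons held 1.75% against 3.35% of placements (p = 0.00200, the smallest possible, n = 4689), introns 42.3% against 40.1% (p = 0.00400) and intergenic sequence 49.6% against 50.3% (p = 0.342). Away from repeats, promoters held 86 of 984 peaks (8.74%), 1.40-fold the share of placements (p = 0.00995, the smallest possible with 200 placements, n = 984). Whether placements in sequence where reads do not map uniquely add to this excess was not tested.

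Fold enrichment of AR peaks was slightly lower inside H3K4me2 peaks than outside them. The medians were 4.35 for 162 peaks inside and 4.71 for 4527 outside, a difference of −0.363 (permutation p = 0.0446). By number of fragments the order was the opposite, as the share inside H3K4me2 was 2.45% (1.80 to 3.26) of peaks with 4 fragments, 3.68% with 5, 4.28% with 6 or 7 and 5.95% (3.44 to 9.48) with at least 8. Without promoter peaks the difference in fold was −0.287 (permutation p = 0.103). Away from repeats the medians were 4.31 for 69 peaks and 3.92 for 915, a difference of 0.389 (permutation p = 0.157). The 162 H3K4me2 peaks with AR were wider and higher than the 60100 others, with median widths of 986.5 and 555 bp (permutation p = 1e-05, the smallest possible) and median fold enrichments of 9.86 and 6.27 (permutation p = 2e-05). Wide peaks are met more often by chance, and the H3K4me2 peaks met by 100 random placements of AR peaks had a mean median width of 1186 bp (924 to 1498) and fold enrichment of 11.3 (8.95 to 15.2).

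Sequence was then compared to see whether AR peaks carried the androgen response element, the palindrome that AR dimers bind. With at most 2 mismatches it was present in 534 of 4689 AR peaks (11.4%, 10.5 to 12.3). In the comparison matched for GC content it was less frequent in AR peaks (356 of 2972, 11.98%, 10.8 to 13.2) than in H3K4me2 peaks without AR (448 of 2972, 15.1%, 13.8 to 16.4; odds ratio 0.767, Fisher's exact p = 0.000552). The reordered control motif was less frequent too (8.51% against 10.5%, Fisher's exact p = 0.0116). Against windows 2 kb away the share of the response element was 11.4% against 12.8% (Fisher's exact p = 0.0144), and against H3K4me2 peaks of unmatched GC content 11.4% against 10.7% (p = 0.163). Away from repeats it was 13.7% of 984 peaks against 12.4% of their flanking windows (odds ratio 1.12, 0.896 to 1.41, Fisher's exact p = 0.321). The interval left out an excess above a ratio of 1.41 and did not exclude a smaller one. With at most 1 mismatch the shares away from repeats were 1.83% and 1.17% (odds ratio 1.58, 0.846 to 2.93, Fisher's exact p = 0.181).

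Of the 20 motifs, 0 were more frequent in AR peaks than in matched H3K4me2 peaks and 8 were less frequent at an adjusted p below 0.05. The 8 were the E-box bound by MyoD (21.2% against 28.5%, odds ratio 0.675, adjusted Fisher's exact p = 1.69e-09), the GC box (2.29% against 4.24%), the TEAD site (8.18% against 11.0%), the NF1 site (0.168% against 0.740%), the Fox site (1.58% against 2.76%), the response element, the single AR recognition hexamer (62.0% against 67.8%) and the reordered control. Against windows 2 kb away, 10 were less frequent and the NRF1 site was more frequent (0.640% against 0.235%, odds ratio 2.74, adjusted Fisher's exact p = 0.00132). Away from repeats, the direct repeat of the hexamer was more frequent than in matched H3K4me2 peaks (15.3% against 9.26% of 734 each, odds ratio 1.76, adjusted Fisher's exact p = 0.0118), and 0 motifs were less frequent. Against flanking windows 0 motifs passed. The NRF1 site stood at 0.203% in these AR peaks and 0.203% in their flanking windows, so its excess over all peaks was absent there. The direct repeat stood at 14.8% against 13.1% (Fisher's exact p = 0.211), and the RUNX site, with the lowest p, at 2.34% against 0.965% (odds ratio 2.46, Fisher's exact p = 0.00456, adjusted p = 0.0912). The response element was present in 22 of 162 AR peaks inside H3K4me2 peaks (13.6%, 8.71 to 19.8) and 512 of 4527 outside (11.3%, Fisher's exact p = 0.377). The difference was 2.27 points, and it was 4.00 points within 50 bp of the summit (Fisher's exact p = 0.0333).

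The last question was which genes lay near AR peaks. A start site of a protein-coding gene was within 100 kb of 2948 AR peaks (62.9%), which gave 2522 genes (11.6% of 21826), and 668 genes when peaks at repeats were left out. Of the 29 lists, 4 lay above the 95th percentile of matched random lists, against 1.45 expected at 5% and 2.465 at the rate of random lists in simulated data. The simulated lists differed from these in size and matching, so 2.465 may differ from the number expected for these lists. The number ranged from 1 to 7 under other settings. Members named beyond the 4 per list that the rule allows make up the counts given and were chosen after their values were seen. Sarcomere genes came first, with 10 of 39 members near an AR peak (4.12 expected, percentile 99.8). They were Myl2, Myl3, Mylk2, Tnni1, Tnnt1, Neb, Obscn, Xirp2, Lmod2 and Lmod3. The highest peak among them lay near Tnnt1, the troponin T of slow fibres (chromosome 7, 4508084 to 4508283, fold 9.42, 11 fragments), at an AC/GT repeat 6.20 kb from its start site. Away from repeats, 5 sarcomere genes had an AR peak (1.18 expected, percentile 99.7), and these were Myl2, Mylk2, Tnni1, Neb and Lmod2. With peaks in the gene body or up to 5 kb upstream, the sarcomere list held 4 (2.88 expected, percentile 76.3). Acta1, Actn2 and Actn3, which encode skeletal actin and the actinins of the Z disc, had none.

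The list of myostatin, activin and BMP signalling, which restrains and shapes muscle growth, held 11 of 28 genes near an AR peak (5.46 expected, percentile 99.5). They included the receptors Acvr2a, Tgfbr1 and Tgfbr2, the signal transducers Smad1, Smad2 and Smad4, the inhibitors Smad7 and Nog, and Id2 and Id3. Away from repeats, Smad1, Smad4, Smad7 and Id3 remained (1.46 expected, percentile 96.6). The list held 1 gene within 10 kb of a peak (percentile 39.2), 5 with peaks in the gene body (76.0), 0 at a −log10 q of at least 5 (34.0), 0 with response elements alone (21.5) and 5 above the median fold enrichment (98.4). Mstn, which encodes myostatin, had no AR peak. The smooth muscle and pericyte list held 4 of 12 (Rgs5, Mylk, Kcnj8 and Abcc9; 1.53 expected, percentile 97.3). It held 3 within 10 kb (99.3) and 3 with peaks in the gene body (95.7), but 0 away from repeats (32.4) or above the median fold enrichment (30.9). It also held 0 at a −log10 q of at least 5 (45.9) and 0 with response elements alone (40.35). Its percentile was 97.6 without matching, 97.9 matched on territory only and 95.9 matched on gene length. The heat shock and stress list held 5 of 25 (Hspa8, Hspb1, Nfe2l2, Gclc and Txnrd1; 2.19 expected, percentile 96.5), and away from repeats 1, which was Hspa8 (71.4). The heat shock list held 0 within 10 kb (20.5), 0 with peaks in the gene body (9.96) and 3 above the median fold enrichment (98.6). It held 0 at a −log10 q of at least 5 (44.4) and 1 with response elements alone (85.7). Its percentile was 89.3 without matching, 97.4 matched on territory only and 97.3 matched on gene length.

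Of the 25 androgen and glucocorticoid response genes, 4 were near an AR peak (4.33 expected, percentile 44.4). These were Klf9, a hormone-induced Krüppel-like factor, Tmprss2, an androgen-induced protease of prostate, Igf1, a growth factor for muscle, and Pik3r1, a regulatory subunit of PI3-kinase. The Klf9 peak (chromosome 19, 23128346 to 23128553, fold 4.25, 5 fragments) was 12.8 kb from the start site and not at a repeat. Of the 4 peaks near Tmprss2, 1 was not at a repeat (chromosome 16, 97640214 to 97640475, fold 4.71), while the peaks of Igf1 and Pik3r1 were. No AR peak was assigned to Fkbp5, Zbtb16 or Tsc22d3. In the polyamine list 3 of 14 genes had an AR peak (1.73 expected, percentile 83.9). The peaks of Odc1 (chromosome 12, 17485308 to 17485494, fold 4.71, 59.4 kb from the start site) and Smox (chromosome 2, 131459285 to 131459463, fold 3.92, 32.1 kb) were not at a repeat, and those of Azin1 were. Away from repeats the polyamine list stood at percentile 95.5 (2 genes, 0.471 expected). The Odc1 peak rested on 5 fragments and the Smox peak on 4. Under other settings the polyamine list held 0 genes within 10 kb (27.8), 1 with peaks in the gene body (48.6) and 1 with response elements alone (88.4). It held 0 above the median fold enrichment (29.4) and 0 at a −log10 q of at least 5 (45.9). Its percentile was 85.4 without matching, 84.1 matched on territory only and 93.0 matched on gene length. Amd1, Amd2 and Srm, which also act in polyamine synthesis, had no AR peak.

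The other lists lay at or below the 95th percentile in the main setting. The slow fibre list held 4 of 15 genes near an AR peak (percentile 94.3, but 98.5 within 10 kb and 95.7 matched on territory only), all 4 also in the sarcomere list, and the fast fibre list held 1 of 16, Casq1 (64.1). Insulin, IGF and mTOR signalling held 9 of 29 (89.6, but 95.2 matched on territory only, 96.2 matched on gene length and 99.7 without matching), with the highest peak at Insr, the insulin receptor (chromosome 8, 3209665 to 3209828, fold 8.53, at an AC/GT repeat). Neuromuscular junction genes numbered 5 of 20 (87.1, but 95.1 without matching), myogenic transcription factors 8 of 27 (68.3, but 99.5 without matching), circadian clock genes 4 of 22 (66.1) and calcium handling genes 4 of 26 (55.3). Oxidative phosphorylation held 2 of 28 (63.4), glycogen metabolism 3 of 17 (54.0), amino acid and creatine metabolism 3 of 24 (49.0) and fatty acid oxidation 2 of 29 (32.4). Glycolysis held 1 of 21 (21.5), nuclear receptors and coregulators 7 of 34 (20.1) and the dystrophin complex 3 of 24 (15.9). Protein breakdown and autophagy held 1 of 26, Usp14 (4.94), and Fbxo32 and Trim63, the ubiquitin ligases of muscle atrophy, had no AR peak. Among cell types, endothelial markers numbered 5 of 14 (93.1, but 98.4 within 10 kb, 98.9 with peaks in the gene body and 99.0 without matching), adipocyte 3 of 12 (91.6, but 96.5 above the median fold), neuron 4 of 15 (78.3), immune 1 of 14 (51.8, but 95.1 with response elements alone), liver 1 of 15 (50.7), satellite cell 2 of 12 (47.2), tendon and Schwann cell 1 of 12 (23.3) and fibroblast 1 of 15 (11.5). The genes with most AR peaks were Pde4d, a cAMP phosphodiesterase, with 6 (2.58 expected from its territory), and Atp6v1c1, Frmd4a, Iqsec1 and Phf21a with 4 each. All 6 peaks of Pde4d lay at a repeat.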

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

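The tests weighed for the 3 patterns below were all chosen after the results they concern had been seen, and their bounds were set then, including an odds ratio of 1.5 as the size of excess to exclude.

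The AR list held 2 peaks on the mitochondrial genome, outside the chromosomes compared. They spanned positions 73 to 6519 (6447 bp, fold enrichment 2.57, −log10 q 82.2) and 10918 to 16249 (5332 bp, fold enrichment 3.48, −log10 q 151), and the H3K4me2 list held 0 there. They stood out because they are a signal in data that no comparison used.

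Dinucleotide repeats were met by 79.0% of AR peaks. Alignment errors that pile up fragments in both libraries are argued against, since 2.51% (2.03 to 3.07) of the AR repeat peaks overlapped an H3K4me2 peak. This value cannot exclude gaps in the input that both libraries were called against. A gap adds no fragments to the H3K4me2 library, whose peaks started at 6 fragments. Of the AR repeat peaks, 17.4% had the summit within 24 bp of the longest repeat met, against 31.9% of placements that met one (Fisher's exact p = 5.95e-33). This cannot decide whether binding was centred on the repeat, since only uniquely mapped reads were kept. Reads within a repeat may be lost in mapping, which could move summits and peak edges, and the placements carry no such loss. Such loss was not tested, as peak lists alone were analysed. Fragments of the AR library that end at the repeat remain a candidate explanation, since the outer end of the repeat lay within 25 bp of a peak edge in 82.5% of repeat peaks and 37.9% of such placements, and in 79.7% against 30.2% when repeats were chosen by nearness to the summit alone. Runs at peak edges had been noticed before this was measured, so it is not independent evidence. Whether such ends arise from the AR antibody, the beads, library preparation or AR-bound chromatin was not tested, as there was no control immunoprecipitation and no second AR library.

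AR peaks showed no excess of the androgen response element, and dilution by peaks at repeats is argued against as a cover for an odds ratio of 1.5 or more, since away from repeats the odds ratio against flanking windows was 1.12 with an upper limit of 1.41 (Fisher's exact p = 0.321). Dilution by peaks of few fragments stays open, because away from repeats 130 peaks had at least 6 fragments, and their odds ratio against those with 4 or 5 was 0.938 (0.544 to 1.62, Fisher's exact p = 0.892). Over all AR peaks the share was 11.5% with 4 fragments, 12.3% with 5, 10.2% with 6 or 7 and 10.4% with at least 8, and above the median fold the odds ratio against matched H3K4me2 peaks was 0.740, which gives dilution no support, but peaks at repeats rise with fragments and could hide it. A consensus that allows too many mismatches stays open too, with an odds ratio of 1.58 (0.846 to 2.93, Fisher's exact p = 0.181) at 1 mismatch. Recruitment of AR by other factors was tested through their motifs alone, of which 0 passed an adjusted p of 0.05 against flanking windows away from repeats, with the RUNX site lowest (adjusted Fisher's exact p = 0.0912).

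AR peaks overlapped H3K4me2 peaks more often than placements on the chromosome did. For all AR peaks the regional density of both kinds of peak may account for this, since placements within 50 kb left an excess of 1.08-fold (3.45% against a central 95% of 2.75 to 3.69). For the 984 peaks away from repeats it is argued against as the whole source, since the excess was 1.70-fold (7.01% against 3.05 to 5.28). Placements within 50 kb were not kept to sequence where reads map uniquely, which could add to this excess and was not tested. Open chromatin, which yields more fragments in many immunoprecipitations, and AR binding at enhancers both remain untested, as no control immunoprecipitation was available.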

How the results depend on the processing

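Settings that leave out peaks at dinucleotide repeats or keep them alone, the comparison with H3K4me2 peaks met by placements, and all settings of the repeat share were chosen after the results had been seen, and the others were planned. Of 79 alternative settings, 45 kept their side of the threshold or stayed within the range allowed. Among these, 2 differences that had not passed changed sign, the promoter share at 3 kb (0.982-fold) and the response element difference inside H3K4me2 away from repeats (−0.727 points). No paired analysis was possible because each group held 1 library, and no replicate could be left out for the same reason. The repeat share kept its direction in 4 of 4 settings, H3K4me2 peak numbers in 2 of 2 and the start-site difference in 2 of 2 (55.7 and 63.9 points). AR peaks had a median of 5 fragments against 19 for H3K4me2, and whether depth or weak enrichment sets this was not tested. Where no reason is given below, the cause was not tested.

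Several settings changed counts. AR peaks numbered 245 at a −log10 q of at least 5, 1280 above the median fold enrichment, 3013 without those over 50% in soft-masked repeats and 984 away from dinucleotide repeats. Genes with an AR peak numbered 151, 783 and 668 under the first, second and last of these, and 844 within 10 kb. Lists above the 95th percentile numbered 2 with peaks in the gene body, 7 without matching, 1 at a −log10 q of at least 5 and 2 with response elements alone, with 1, 3, 1 and 1 shared with the main 4. Away from repeats they numbered 3, with 2 shared.

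The overlap of AR with H3K4me2 missed the threshold with H3K4me2 peaks of a −log10 q of at least 5 (2.77%, p = 0.0759, n = 4689), placements within 50 kb (3.45%, p = 0.344), AR peaks of a −log10 q of at least 5 (3.27%, p = 0.735, n = 245) and AR peaks above the median fold (3.52%, p = 0.106, n = 1280). The last pair had fewer peaks. Against 1.28 in the main setting, the folds over placements were 1.18, 1.08, 1.18 and 1.304, so the last excess did not shrink. For repeat peaks alone the overlap was 0.938-fold that of placements not kept to repeats, a change of direction that did not pass (2.51%, placement p = 0.579, n = 3705). The promoter share passed away from repeats (8.74%, p = 0.00995, the smallest possible with 200 placements, n = 984). By permutation, the lower fold inside H3K4me2 missed the threshold with overlap of 50% of the peak (−0.363, p = 0.0727), with the summit inside (−0.363, p = 0.0693) and without promoters (−0.287, p = 0.103). Away from repeats the difference changed direction without passing (0.389, permutation p = 0.157). Against H3K4me2 peaks met by placements, those with AR differed by −199 bp in width and −1.39 in fold. Both medians (986.5 bp and 9.86) lay within the ranges of the placements (924 to 1498 bp and 8.95 to 15.2). The excess in width and fold was thus lost, and no opposite difference was shown.

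By Fisher's exact test, the response element share in AR peaks reversed at 0 mismatches (0.135% against 0.0673%, p = 0.687), without GC matching (11.4%, p = 0.163), and away from repeats against flanks (13.7%, p = 0.321; 1.83% at 1 mismatch, p = 0.181). By the same exact test the lower share of the response element missed the threshold at 1 mismatch (1.08%, odds ratio 0.778, p = 0.346), at a −log10 q of at least 5 (11.2%, odds ratio 0.735 against 0.767 in the main setting, p = 0.333) and away from repeats (14.0%, odds ratio 0.897, p = 0.507). It held without peaks over 50% in soft-masked repeats (11.1%, exact p = 0.000274). Motifs more frequent in AR peaks numbered 1 against flanks and 1 away from repeats, in place of 0. The response element difference inside H3K4me2 passed within 50 bp of summits (4.00 points, Fisher's exact p = 0.0333).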

Other observations

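The comparisons of peak width by list, of motifs in distal H3K4me2 peaks and of chromosomes were all chosen after the data had been seen, and they are given as values.

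H3K4me2 peaks at start sites were widest for genes of fast fibres and glycolysis. The median width over marked members was 3.91 kb for the fast fibre list (14 genes) and 3.19 kb for glycolysis (20 genes), both at percentile 100 of random lists of marked genes, whose median was 1.54 kb. Among fast fibre and glycolytic genes chosen after their values were seen were Pvalb, parvalbumin, the calcium buffer of fast fibres (10842 bp), Tnni2, fast troponin I (6087 bp), Aldoa, aldolase A (7496 bp), and Hk2, hexokinase 2 (3692 bp). The fast fibre genes Myh4 (730 bp) and Myl1 (319 bp) had narrow peaks, and Myh1 and Myh2 had none at their start sites. Pygm, glycogen phosphorylase of muscle, had 8872 bp, while the median of the glycogen metabolism list was 1.67 kb (percentile 71.5). Circadian clock genes (3.06 kb), androgen and glucocorticoid response genes (2.98 kb), calcium handling genes (2.92 kb) and sarcomere genes (2.56 kb) also stood at percentile 100. Of the 20 pathway lists, 14 lay above percentile 98, so wide peaks were shared by most of them. Slow fibre genes had 1.38 kb (percentile 25.6), oxidative phosphorylation genes 1.58 kb (61.5), satellite cell markers 1.38 kb (25.1), endothelial markers 0.829 kb (0.335) and neuron markers 0.743 kb (0.110).

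H3K4me2 peaks over 1 kb from a start site were compared for motifs with flanking windows of the same GC content (33429 each). The E-box bound by MyoD was present in 35.5% against 32.4% (odds ratio 1.15, adjusted Fisher's exact p = 1.03e-16), and the MEF2 site in 0.347% against 0.194% (odds ratio 1.79, adjusted p = 0.00121). MEF3, SRF and TEAD sites did not pass, with odds ratios of 0.916, 0.856 and 1.03 (adjusted Fisher's exact p = 0.0834, 0.135 and 0.245). NF1 and AP-1 sites had odds ratios of 1.37 (adjusted Fisher's exact p = 0.00299) and 1.14 (adjusted p = 0.00370). The NFY site was less frequent (5.48% against 6.33%, odds ratio 0.858, adjusted Fisher's exact p = 3.4e-05). The single AR recognition hexamer and the GC box, NRF1, Fox and RUNX sites also passed, with odds ratios of 1.05, 1.07, 1.28, 1.14 and 1.17. The androgen response element was less frequent (12.6% against 13.2%, odds ratio 0.9497, adjusted Fisher's exact p = 0.0480), while its reordered control was more frequent (odds ratio 1.10, adjusted p = 0.00182). Odds ratios near that of the control, as for the E-box and AP-1, thus also arose for a sequence no factor was chosen for.

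The X chromosome held 0.569 AR peaks per Mb, against 1.92 over the autosomes (lowest 1.72, highest 2.46), and 5.84 H3K4me2 peaks per Mb against 24.8 (16.9 to 42.7). The ratios to the autosomes were 0.297 and 0.236. The Y chromosome held 0 AR peaks and 5 H3K4me2 peaks.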
